A study of Homo sapiens and Mus musculus with 8 samples.

How the data were processed

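The series holds 8 samples. Bulk RNA was sequenced from 3 biopsies of normal human olfactory mucosa (OM) and 3 biopsies of olfactory neuroblastoma (ONB), numbered 1, 2 and 5. Droplet single-cell RNA was sequenced from 1 ONB specimen, which was dissociated and frozen first, and from 1 pool of mouse OM cells. Per the labels, the mouse cells were sorted against neurons and sustentacular cells and then divided into 4 libraries. The labels call the human bulk samples biopsy specimens and do not state that each came from a separate donor, so the p-values below measure the spread between specimens.

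For the bulk samples the authors deposited a table of raw read counts per gene symbol, with no normalization. Per the submitters' processing notes, the reads were aligned with STAR 2.5.2 to hg19. The counting tool, the annotation and the strand setting were not given in the sources used here, although the labels name a stranded library kit and state that all bulk samples were processed together. For both single-cell samples the authors deposited matrices of UMI counts per gene and cell, not scaled per cell. Per the submitters' processing notes, the mouse matrix was made with Cell Ranger 2.1.1 and mm10, while the header of the matrix names version 3.0.2. Per the labels, the mouse libraries were normalised to depth and aggregated. The human matrix was made with Cell Ranger 3.0.2 and GRCh38, and its barcodes carry suffixes 1 to 4 of unstated meaning. The other deposited files of each matrix hold cell barcodes and gene symbols, with no measurement.

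The groups, tests, gene lists, marker lists, the rule for named genes and most alternatives were fixed before the data were examined. The thresholds that turn marker scores into cell class names, and 5 alternatives, were chosen after seeing the data.

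The bulk table holds 26475 genes. XIST and the genes of the Y chromosome, 108 in all, were left out, and 26367 genes stayed. Genes with low counts were removed with filterByExpr of edgeR 4.0.16 (minimum count 10), which left 17446 genes. Libraries were scaled with TMM. ONB was compared with OM by edgeR's quasi-likelihood test, 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 fold changes are ONB minus OM. CPM values use the TMM-scaled library sizes, and errors are SDs over the 3 libraries of a group. The floor of a group is 3 counts over its 3 libraries. Intervals of ratios are exact conditional binomial intervals and, like all intervals and floors given here, cover counting error only, since reads are not independent molecules and cells of 1 specimen are not replicates.

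Of 29 gene lists fixed in advance, 28 had at least 3 tested members. The mitochondrially encoded genes are absent from the bulk table, so that list has no result. Each list was tested on log2 CPM (prior count 2) with camera of limma 3.58.1 and a preset correlation of 0.01, adjusted over the 28 lists. A camera test compares a list with all other genes. Each list was also tested with a correlation estimated per list and with fry, which asks whether the members move, on balance, one way. Member counts are given over all genes and adjusted over the list alone.

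Named genes were chosen by a rule. It takes the 8 higher and the 8 lower genes with the largest fold change among genes past the threshold, with a mean log2 CPM of at least 3 and no overlap between the groups. It leaves out immunoglobulin, T cell receptor and olfactory receptor genes and uncharacterised loci. It adds a fixed set of lineage genes whatever their values, up to 3 further members of each list that passed, and up to 5 leading genes of each cell cluster. Some genes that the rule names are not reported. Genes outside the rule are marked as chosen after their values were seen.

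Barcodes with fewer than 1000 UMIs, fewer than 500 genes or more than 10% (mouse) or 20% (human) mitochondrial UMIs were removed with scanpy 1.11.5. Doublets were scored against simulated doublets (2 per barcode), and a fixed share of the highest scores, 0.8% per 1000 barcodes of a library, was removed. Cells were clustered on 2000 variable genes, 30 principal components and 20 neighbours with leidenalg 0.10.2 at resolution 1. The markers of each class were scored in each cluster as the mean log2 ratio (5 CPM added) to the mean of the other clusters. A cluster was named after its highest class if the score was at least 1.2 and at least 3 markers were raised 2-fold at 10 CPM or more. It stayed unnamed if another class (outside the neural lineage for neural clusters) scored at least 0.75 of that, if markers of other classes led its top 10 genes by 2 or more, or if its median UMI count was under 0.333 of the sample's median with no marker among those genes. Since most human cells are of 1 kind, human clusters that had no class in that step were scored against the pool of the named and mixed clusters, with a minimum of 0.5. Class names end in "-like", since they rest on RNA alone. Shares carry exact Clopper-Pearson 95% intervals and CPM of summed UMIs carry exact Poisson 95% intervals. There is 1 sample of each kind, so no test was made.

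The signature of a mouse class is the 50 genes with the largest fold over the highest other class and a CPM of at least 50. Human genes were matched by upper-case symbol, and 15843 matched. Signatures were tested in the bulk libraries with camera, adjusted over 12 signatures. In the human cells, the median log2 ratio of each signature was set against 10000 random lists of equal size and expression.

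Alternatives covered the scaling, the low-count filter, the tool (DESeq2 1.42.0 and limma-voom), a test against a fold of 1.5, a block on the specimen number, leaving out each library, signature size, cell cycle genes, cluster resolution, cell filters and doublets. The 5 added ones are a mitochondrial limit of 30%, the mouse immature neuron clusters taken apart, all other cells as base of the human ratios, a second clustering of 2 human clusters, and a different naming of 1 human cluster. Other software was R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

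The steps were tested on simulated data. With 3 libraries against 3 and 17197 genes, 11% of 100 genes with a 4-fold change and 66% of 100 genes with a 16-fold change were recovered, and 4 of 81 calls were false (4.94%). No other gene was changed, while 4170 genes were called in the real data. The adjusted threshold depends on how many genes change, so these rates do not carry over to the real comparison. In 6 simulated classes of 300 cells, all cells fell into the right class, and 96.2% of 79 mixed doublets lay among the highest scores. These cells were drawn from the summed profiles of mouse classes that the same steps had named, with no spread within a class beyond sampling. They check that the steps run and do not test the names of the real clusters.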

Results

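The series measured RNA in the olfactory mucosa (OM), the lining of the upper nose that holds the olfactory neurons, and in olfactory neuroblastoma (ONB), a tumour that arises there. The bulk libraries of OM 1, OM 2 and OM 3 held 17316796, 15704034 and 12741913 counts, and those of ONB 1, ONB 2 and ONB 5 held 21767608, 13715259 and 25631356 counts. The 10 most abundant genes took between 4.25% and 6.03% of the counts of a library. The mouse OM sample gave 25800 barcodes, of which 23305 cells were kept with a median of 3488 UMIs and 1653 genes. The human ONB specimen gave 7348 barcodes, of which 4728 cells were kept with a median of 10452 UMIs. In that specimen 2151 barcodes (29.3%) were over the mitochondrial limit. The first principal component of the bulk libraries carried 61.1% of the variance and separated the 3 ONB from the 3 OM libraries.

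The bulk comparison asks how the transcriptome of ONB differs from that of the tissue it arises in. NEUROD1, HES6, NKX2-2 and SCG2 were among the genes more abundant in ONB. NEUROD1, a transcription factor that drives neuronal differentiation, rose from 1.17 ± 1.09 CPM in OM to 250 ± 175 CPM in ONB (SD, n = 3 each). HES6, a factor of neural progenitors that counters HES1, rose from 19.2 ± 12.9 to 1322 ± 795 CPM. NKX2-2, a homeobox factor of neural and endocrine progenitors, rose from 0.157 ± 0.272 to 158 ± 57.7 CPM, and SCG2, a granin of secretory granules, rose from 5.96 ± 4.15 to 714 ± 515 CPM. The log2 fold changes were 7.69 (SE 1.22, adjusted p = 0.0110) for NEUROD1, 6.10 (SE 0.77, adjusted p = 0.00798) for HES6, 9.76 (SE 1.08, adjusted p = 0.00715) for NKX2-2 and 6.90 (SE 0.91, adjusted p = 0.00862) for SCG2 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each of these genes was higher in all 3 ONB libraries than in any OM library. The NEUROD1 call was lost without OM 2 (adjusted p = 0.0505; 0.0177 to 0.0505 over the 6 fits that leave out a library).

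The 8 genes with the largest rises under the rule were MIR7-3HG, NKX2-2, GABRA5, SNTG1, AVPR1B, CACNG5, ESPNL and KCNG2. MIR7-3HG, the host transcript of a microRNA of endocrine and neural cells, had 121 ± 38.4 CPM in ONB against 0.105 ± 0.181 CPM in OM, a log2 fold change of 9.92 (SE 0.96, adjusted p = 0.00703). AVPR1B, a vasopressin receptor of pituitary corticotrophs, had 2180 counts in ONB and 2 in OM, a ratio of 937 (259 to 7741). GABRA5, a GABA receptor subunit, had 1187 counts in ONB and 1 in OM (ratio 1020, 183 to 40330), and CACNG5, a regulator of neuronal ion channels, had 1298 and 1 (ratio 1116, 200 to 44099). SNTG1, a neuronal syntrophin, had 1354 and 1 (ratio 1164, 209 to 46000), and KCNG2, a potassium channel subunit, had 1625 and 2 (ratio 698, 193 to 5771). ESPNL, an espin-like protein of actin bundles, had 1236 CPM in ONB 1 and 162 and 149 CPM in ONB 2 and ONB 5, against 0.826 ± 0.287 CPM in OM. Each of the 8 genes was past the threshold in all 6 fits that left out a library.

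**Figure D1:**
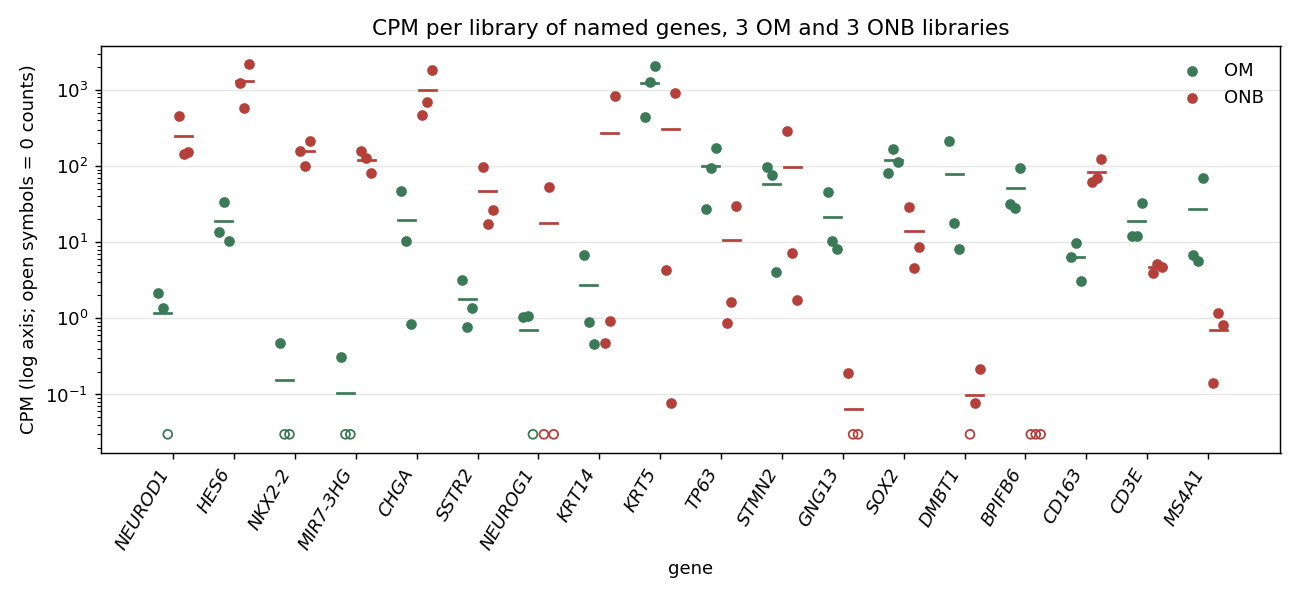
Levels of 18 named genes in the bulk libraries, in CPM on a log axis; points are libraries, bars are group means, and open symbols are libraries with 0 counts, drawn at 0.03 CPM. HES6 lies between 575 and 2158 CPM in the ONB libraries and between 10.3 and 34.0 CPM in the OM libraries.

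The list of neuroendocrine genes rose as a group: 6 of 12 tested members were higher and 0 lower over all genes, and 8 were higher adjusted over the list alone (median log2 fold change 3.29, camera adjusted p = 0.00117; adjusted p = 0.531 with an estimated correlation, and 0.0695 with fry). CHGA, the chromogranin that pathologists stain for, rose from 19.3 ± 24.3 to 997 ± 737 CPM (log2 fold change 5.69, adjusted p = 0.0304), higher in all 3 ONB libraries than in any OM library. Its call was lost without OM 2 (adjusted p = 0.107), without ONB 1 (0.0573) and without ONB 5 (0.0612; 0.0314 to 0.107 over the 6 fits). SYP, a synaptic vesicle protein (log2 fold change 2.68, adjusted p = 0.0583), INSM1, a factor of endocrine and neuronal differentiation (3.65, 0.0743), and NCAM1, a neural adhesion molecule (1.16, 0.313), did not pass. SYP passed with DESeq2 (0.00502), with limma-voom (0.0234) and without OM 1 (0.0201), and INSM1 passed with DESeq2 (0.0118), with limma-voom (0.0465) and without OM 3 (0.0274). SSTR2, a somatostatin receptor used as a target of imaging and therapy, rose from 1.78 ± 1.26 to 46.9 ± 43.6 CPM (log2 fold change 4.70, adjusted p = 0.0157). The SSTR2 call was lost without OM 2 (0.0584) and without OM 3 (0.0561; 0.0181 to 0.0584 over the 6 fits). SSTR1, of the same family and outside the naming rule, had a log2 fold change of 5.78 (adjusted p = 0.0180) and was chosen after its values were seen. Of the 3 tested somatostatin receptors 2 were higher, over all genes and adjusted over the list alone, and the list did not pass (median log2 fold change 4.70, camera adjusted p = 0.158; 0.0375 without ONB 5, and 0.0375 to 0.531 over the alternatives).

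Markers of olfactory stem and progenitor cells did not move together. Of 12 globose basal cell genes, which mark the dividing progenitors of the epithelium, NEUROD1 and HES6 were higher and SOX2 lower, over all genes and adjusted over the list alone, and the list did not pass (median log2 fold change 1.03, camera adjusted p = 0.217; 0.0175 with fry, and 0.0175 to 0.496 over the alternatives). SOX2, a factor of neural and epithelial stem cells, fell from 121 ± 43.6 to 14.0 ± 12.9 CPM (log2 fold change -3.11, adjusted p = 0.0239), and its call was lost without OM 2 (0.0795), OM 3 (0.0594) and ONB 5 (0.0660; 0.0268 to 0.0795 over the 6 fits). KIT, a progenitor receptor, had a log2 fold change of -0.90 (adjusted p = 0.371), and LGR5, a stem cell receptor, 0.61 (0.350). NEUROG1, a neurogenic factor of progenitors, had 53.5 CPM in ONB 2 and 0 counts in ONB 1 and ONB 5 (log2 fold change 4.61, adjusted p = 0.238; -6.74 without ONB 2). Of 12 immature neuron genes STMN1, CRMP1 and GNG8, which were chosen after their values were seen, were higher and 0 were lower, over all genes and adjusted over the list alone (median log2 fold change 0.79, camera adjusted p = 0.194). GAP43, a growth cone protein, had a log2 fold change of -0.83 (adjusted p = 0.669). STMN2, a tubulin regulator of growing axons, had one of 0.74 (0.776), with 286 CPM in ONB 1 and -3.79 without that library.

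The fixed list of mature olfactory neuron genes was lower in ONB. The mouse mature neuron signature did not pass, with 5 of 45 genes higher and 6 lower (camera adjusted p = 0.453). GNG13, a G protein subunit of olfactory and taste signalling, fell from 21.2 ± 20.9 to 0.0637 ± 0.110 CPM (log2 fold change -8.13, adjusted p = 0.0127), and EBF4, a factor of olfactory neurons, fell from 78.3 ± 4.79 to 16.5 ± 4.79 CPM (-2.25, 0.00826). RTP1, a chaperone that brings odorant receptors to the membrane, had 751 counts in OM and 2 in ONB, a ratio of 437 (121 to 3614). OMP, the marker of mature olfactory neurons, was under the count filter, with 9.33 ± 11.3 CPM in OM and 0.136 ± 0.160 CPM in ONB. Of 11 tested members 4 were lower and 1 higher, and adjusted over the list alone 7 were lower and 1 higher (median log2 fold change -2.68, camera adjusted p = 0.0156; adjusted p = 0.531 with an estimated correlation; 0.0695 with fry; 0.0572 without OM 1, and 1.93e-04 to 0.531 over the alternatives). The higher one was CNGA2, a channel of odorant transduction (log2 fold change 4.51, adjusted p = 0.0291), chosen after its values were seen. Of 10 tested olfactory receptors 6 were lower and 1 higher, over all genes and adjusted over the list alone, with a median log2 fold change of -4.86, or -4.42 with members at 0 counts held at the floor (camera adjusted p = 0.00873; adjusted p = 0.496 with an estimated correlation).

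The epithelium and glands of the nose were lower as well. BPIFB6 and BPIFB3, lipid-binding proteins of the nasal lining, had 51.1 ± 36.6 and 456 ± 286 CPM in OM. BPIFB6 had 0 counts in ONB and was at least 971-fold lower against the floor of the group, and BPIFB3 fell to 0.0997 ± 0.0866 CPM (log2 fold change -12.19, SE 1.16, adjusted p = 0.00703). LCN15, a lipocalin, fell from 637 ± 319 to 0.755 ± 0.507 CPM (-9.74, SE 0.93, adjusted p = 0.00703), and SCGB1C1, a secretoglobin, had 799 CPM in OM 1, 61.4 and 166 CPM in OM 2 and OM 3, and 0.185 ± 0.213 CPM in ONB (-10.69, SE 1.47, adjusted p = 0.00876; 0.050025 with limma-voom, where the call is lost). GSTA2, a glutathione transferase, had 8520 counts in OM and 3 in ONB (ratio 3304, 1130 to 16026), WFDC6, a protease inhibitor, 979 and 1 (ratio 1139, 204 to 45035), and CYP4F12, a cytochrome P450, 2018 and 3 (ratio 783, 267 to 3798). GSTA2 and SCGB1C1 have close paralogs, and how reads shared with them were counted is not known. DMBT1, a mucosal glycoprotein, had 212 CPM in OM 1, 17.9 and 8.15 CPM in the other OM libraries and 0.0977 ± 0.109 CPM in ONB (-9.49, SE 1.79, adjusted p = 0.0156), and its call was lost without ONB 1 (0.0522; 0.0261 to 0.0522 over the 6 fits) and with limma-voom (0.108).

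Lists of mucosal cell types passed in the same direction. Of 10 ciliated cell genes 8 were lower, 9 adjusted over the list alone (median log2 fold change -4.06, camera adjusted p = 0.00117), with CAPS, a calcium-binding protein of cilia-bearing cells, falling from 838 ± 450 to 35.1 ± 25.4 CPM. Of 10 Bowman's gland genes 5 were lower, 7 adjusted over the list alone (-3.73, 0.00462). Of 10 sustentacular cell genes 3 were lower, 5 adjusted over the list alone (-2.54, 0.00456), among them CYP4B1, a detoxifying cytochrome P450, with 550 ± 300 CPM in OM and 27.2 ± 10.6 in ONB. Of 10 microvillar and tuft cell genes 4 were lower, 7 adjusted over the list alone (-2.82, 0.00374), among them FOXI1, the factor of ionocytes, with 7.40 ± 1.18 and 0.0877 ± 0.113 CPM. Of 8 respiratory secretory genes 0 were lower or higher, over all genes and adjusted over the list alone, yet the list passed as a group (0.0158), with a median log2 fold change of -3.19. These 5 lists had 0 members higher, and each had an adjusted p = 0.496 with an estimated correlation. With fry the sustentacular (0.0504) and respiratory secretory (0.0647) lists did not pass.

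Genes of horizontal basal cells, the reserve stem cells of the epithelium, had a median log2 fold change of -1.53, with 2 of 10 lower and 1 adjusted over the list alone (camera adjusted p = 0.0475; adjusted p = 0.701 with an estimated correlation, and 0.201 with fry). The call of this list was lost without OM 2 (0.0631), OM 3 (0.0925), ONB 1 (0.196) or ONB 2 (0.171), and with RLE scaling (0.0553), over a range of 0.00109 to 0.701. ITGB4, an integrin of the basal membrane, fell from 381 ± 146 to 28.3 ± 20.3 CPM (log2 fold change -3.75, adjusted p = 0.0149; 0.0547 without ONB 1). KRT5, a basal keratin, had 919 CPM in ONB 5 and 4.35 and 0.0779 CPM in ONB 1 and ONB 2, against 1247 ± 801 CPM in OM (log2 fold change -2.02, adjusted p = 0.516; -9.09 and 0.0320 without ONB 5). KRT14, its partner keratin, had 822 CPM in ONB 5 and at most 6.76 CPM in each other library (6.64, 0.126; -1.94 without ONB 5). TP63, the factor of basal cells, had a log2 fold change of -3.18 (adjusted p = 0.130; 0.0241 without ONB 5 and 0.0255 with DESeq2).

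**Figure D2:**
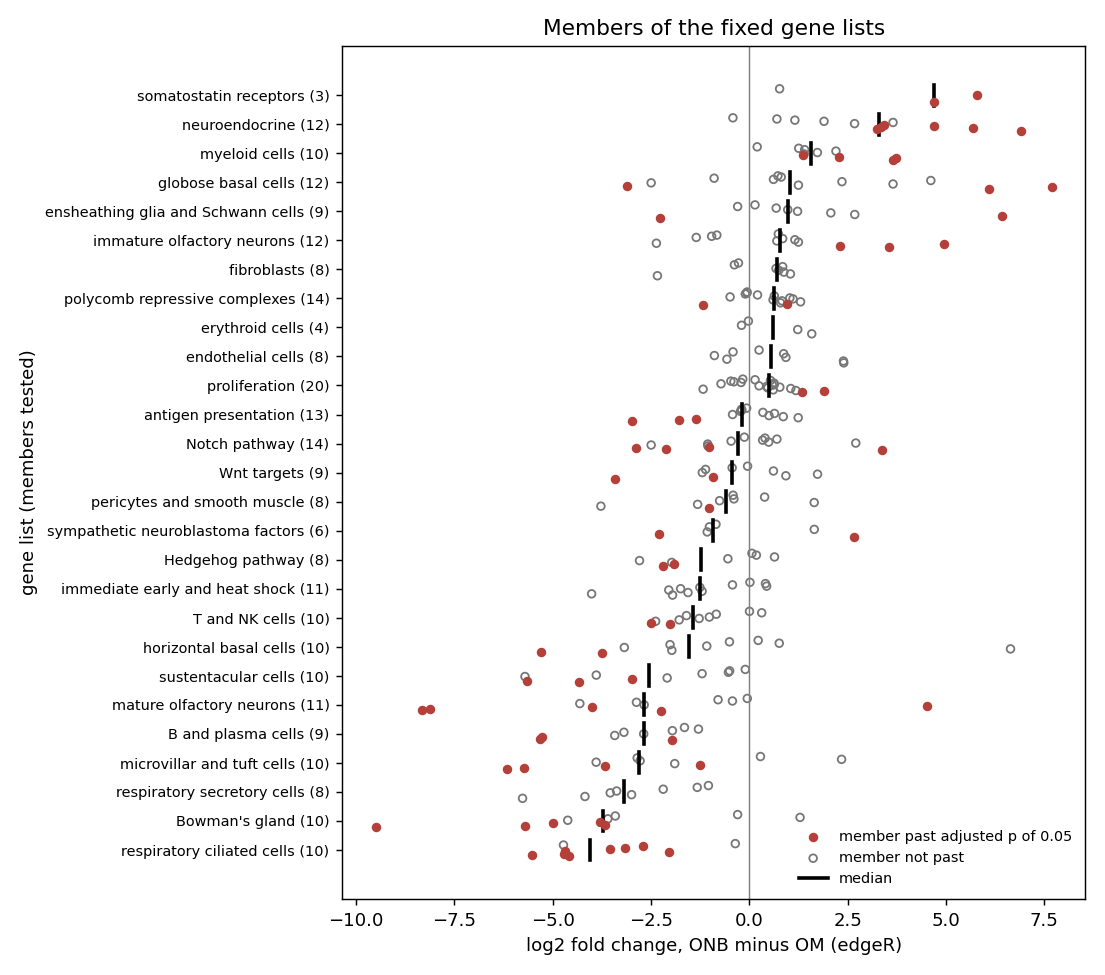
Log2 fold change (ONB minus OM) of each tested member of the fixed gene lists except the olfactory receptors; filled points are past the adjusted threshold of 0.05, open points are not, and black bars are medians. The medians run from -4.06 for ciliated cells to 4.70 for somatostatin receptors.

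The fixed lists of immune genes parted by lineage. The mouse monocyte or dendritic signature did not rise with the myeloid list. Of its 44 tested genes 1 was higher and 4 lower (median log2 fold change -0.36, camera adjusted p = 0.158). CD163 and MRC1, scavenger receptors of macrophages, rose from 6.36 ± 3.29 to 84.7 ± 34.2 CPM (log2 fold change 3.73, adjusted p = 0.00901) and from 3.27 ± 1.12 to 41.1 ± 5.14 CPM (3.65, 0.00703), each higher in all 3 ONB libraries than in any OM library. Of 10 myeloid genes 4 were higher and 0 lower, 7 adjusted over the list alone (median log2 fold change 1.57, camera adjusted p = 0.00374; adjusted p = 0.531 with an estimated correlation). Of 9 B and plasma cell genes 3 were lower and 0 higher, 6 adjusted over the list alone (-2.69, 0.00374; adjusted p = 0.496 with an estimated correlation). Of 10 T and NK cell genes 2 were lower and 0 higher, and 0 adjusted over the list alone (-1.44, 0.0179; adjusted p = 0.496 with an estimated correlation; 0.0652 with fry; 0.0799 without ONB 1, and 0.00668 to 0.496 over the alternatives). The 2 genes, CD3E, a subunit of the T cell receptor complex (log2 fold change -2.03, adjusted p = 0.0333), and CD2, an adhesion molecule (-2.51, 0.0469), passed in 0 and 1 of the 6 fits that left out a library, with adjusted p up to 0.0930 without OM 3 for CD3E and up to 0.121 without OM 3 for CD2.

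Growth and pathway lists did not pass. Of 20 proliferation genes 2 were higher (1 adjusted over the list alone; camera adjusted p = 0.249), and MKI67 and TOP2A, markers of dividing cells, had log2 fold changes of -0.47 (adjusted p = 0.627) and 1.05 (0.199). Of 14 polycomb genes 1 was higher and 1 lower, over all genes and adjusted over the list alone (0.223; 0.0303 with fry, and 0.0303 to 0.496 over the alternatives), and EZH2, the polycomb methyltransferase, had a log2 fold change of 0.83 (adjusted p = 0.0728; 0.0389 with DESeq2). Of 14 Notch genes 1 was higher and 3 lower (0.591), of 8 Hedgehog genes 2 lower (0.158; 0.0303 with fry, and up to 0.496), of 9 Wnt target genes 2 lower (0.497), of 6 sympathetic neuroblastoma factors 1 higher and 1 lower (0.696), and of 13 antigen presentation genes 3 lower (0.497), and each count was equal adjusted over the list alone. The lower Notch genes, chosen after their values were seen, were NOTCH1, NOTCH3 and HES1, a receptor pair and the repressor they induce, and the higher one was HES5, a related repressor. Of 11 immediate early and heat shock genes 0 passed (0.194; 0.0237 without OM 2, and 0.0237 to 0.764 over the alternatives).

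No list of supporting tissue passed the threshold, but with the specimen number as a block the fibroblast list passed as lower (adjusted p = 0.0197). Of 9 genes of ensheathing glia and Schwann cells 1 was higher and 1 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.426), and S100B, a glial calcium-binding protein, had a log2 fold change of 0.98 (adjusted p = 0.521; -0.41 without ONB 2). Of 8 pericyte and smooth muscle genes 1 was lower, 0 adjusted over the list alone (0.392). Of 8 endothelial genes (0.845), 8 fibroblast genes (0.845) and 4 erythroid genes (0.80002), 0 passed over all genes or adjusted over the list alone. The median and the mean of the erythroid list were above 0 (0.60 and 0.65) while its camera and fry tests pointed down.

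In all, 2135 genes were higher and 2035 lower in ONB among 17446 tested. The groups did not overlap for 8382 genes (48.0%), where chance gives 10%. Leaving out a library changed the numbers of higher and lower genes most without OM 2, to 569 and 764, and also by over 1.5 times without OM 1 (1018 and 1217), OM 3 (897 and 929), ONB 1 (1025 and 960) and ONB 5 (1350 and 1261), with 0 genes called in the opposite direction. Of the 50 named genes past the threshold, 26 passed in each of these 6 fits.

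The mouse cells give a map of the lineage that the tumour can be set against. Markers of successive neuronal stages differed between the classes. Neurod1 and Hes6 were at 840 (818 to 862) and 1454 (1425 to 1483) CPM in globose basal cell-like cells. Neurod1 was also among the top 10 genes of an immature neuron-like cluster of 943 cells, so it does not separate these 2 classes. Gap43 and Gng8 peaked in immature neuron-like cells, and Omp reached 8025 CPM in mature neuron-like cells. Mature neuron-like cells made up 46.4% of the kept cells (45.8% to 47.0%; 45.6% to 47.5% over the 4 libraries), immature neuron-like cells 11.4% (10.96% to 11.78%) and globose basal cell-like cells 2.43% (2.24% to 2.64%; 567 cells). Tuft-like microvillar cells, with Il25 and Ptgs1 among their leading genes, made up 14.8% (14.4% to 15.3%), and ionocyte-like microvillar cells, led by Coch, 9.85% (9.47% to 10.2%). Sustentacular-like cells made up 5.13% (4.85% to 5.42%), T or NK-like cells 3.91% (3.67% to 4.17%), and horizontal basal cell-like cells, with Krt5 at 1168 (1076 to 1265) CPM, 0.429% (0.349% to 0.522%; 100 cells). Monocyte or dendritic-like, neutrophil-like, erythroid-like and respiratory secretory-like cells each made up between 0.378% and 0.674%, and 7 unnamed clusters held 3.67%. The cells had been sorted against neurons and sustentacular cells, so these are shares of the sorted cells, not of the tissue. Omp stood at up to 1510 CPM in named classes outside the neuronal lineage, so its presence alone does not mark a neuron here.

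**Figure D3:**
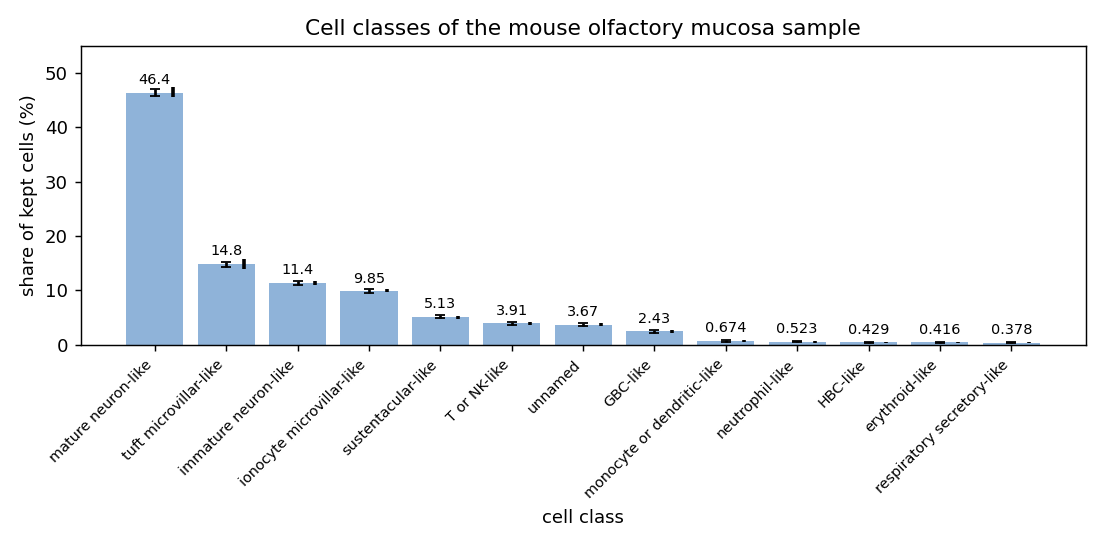
Share of the 23305 kept mouse cells in each class, in percent; bars carry exact 95% intervals, and thin black lines span the 4 libraries of the pool. Mature neuron-like cells stand at 46.4% and the 5 smallest named classes under 1%.

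The signatures of the mouse classes ask which of these cell types the ONB libraries hold more or less of than normal mucosa. The respiratory secretory, sustentacular, T or NK and horizontal basal signatures were lower in ONB, and 0 signatures were higher. Of 45 secretory signature genes 23 were lower and 0 higher, 30 and 1 adjusted over the list alone (camera adjusted p = 2.88e-08; adjusted p = 0.510 with an estimated correlation). This signature also holds genes of ciliated cells, so its fall cannot be assigned to secretory cells alone. Among its genes, chosen after their values were seen, CDHR4, CCDC17, CDHR3, CCDC78 and DNAH5, linked to cilia, had log2 fold changes of -7.12, -6.78, -5.51, -5.54 and -3.54 and passed, and SNTN (adjusted p = 0.0656) and CCDC113 (0.0707), linked to cilia as well, did not. The secretory mucin MUC5B passed (-5.00, 0.0292), and the secretory genes BPIFA1 (0.0915), BPIFB1 (0.172) and SCGB3A1 (0.301) did not. Of 46 sustentacular genes 17 were lower and 3 higher, 21 and 4 adjusted over the list alone (camera adjusted p = 9.87e-05, and 0.336 with an estimated correlation). Signatures were built over named classes only. Bpifb4, the top gene of this signature, stood at 16784 CPM in an unnamed mouse cluster of 52 cells, against 66.3 CPM in all other cells. The fall of the sustentacular signature therefore cannot be assigned to sustentacular cells alone. Of 45 T or NK genes 12 were lower and 3 higher, over all genes and adjusted over the list alone (1.72e-04; adjusted p = 0.649 with an estimated correlation, and 0.0729 with fry). Of 50 horizontal basal genes 6 were lower and 4 higher, 5 and 4 adjusted over the list alone (0.0198; adjusted p = 0.683 with an estimated correlation, and 0.175 with fry), a call that was lost without OM 3 (0.113), ONB 1 (0.0650) or ONB 2 (0.0807; 1.93e-04 to 0.683 over the alternatives). Of 49 globose basal genes 10 were higher and 5 lower, 11 and 5 adjusted over the list alone (0.481), and of 49 immature neuron genes 7 were higher and 2 lower, 5 and 2 adjusted over the list alone (0.158; 0.0296 without OM 1). With signatures of 100 genes both passed as higher (0.00721 and 0.00626), over ranges up to 0.788 and 0.733. Mature neuron (0.453), tuft (0.133), ionocyte (0.438), monocyte or dendritic (0.158), neutrophil (0.964) and erythroid (0.411) signatures did not pass. For the neutrophil signature camera pointed down although the median and the mean of its genes were above 0, and for the ionocyte and erythroid signatures the median and the mean differed in sign. Among bulk genes assigned to the mouse class with the highest level, globose basal genes were 18.05% of the 942 higher genes and 11.7% of the 5934 tested ones. Mature neuron genes were 22.8% and 18.7%, and immature neuron genes 14.1% and 10.2%, of the same. Genes of the respiratory secretory class were 9.87% of the 608 lower genes and 3.19% of the tested ones, and no test of these shares was made.

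Most cells of the human ONB specimen carried neuroendocrine and progenitor genes together. Neuroendocrine-like cells made up 78.1% of the kept cells (76.9% to 79.3%; 3692 cells in 9 clusters). Over the 4 barcode suffixes, these cells made up from 73% to 81.7%, a wider span than that interval. They held HES6 at 1981 CPM, NEUROD1 at 760 (752 to 768), CHGA at 592, CHGB, a second granin, at 895, GNG8, a G protein subunit of immature olfactory neurons, at 458, NKX2-2 at 196 and SSTR2 at 140 CPM. In the same cells OMP and GNG13 had 0 UMIs, which allows up to 0.07 CPM, STMN2 had 3 UMIs and NEUROG1 was at 30.6 CPM. On GRCh38, HES6 lies on chromosome 2 from 238238267 to 238240662, NEUROD1 on chromosome 2 from 181673088 to 181680876, and CHGA on chromosome 14 from 92923080 to 92935293, each a protein-coding gene. Glia-like cells, with S100B at 963 CPM, made up 1.502% (1.17% to 1.89%; 71 cells). Clustered again, a step chosen after seeing the data, these 71 cells parted into 38 and 33. In sum the 38 had HES6 at 1104, NEUROD1 at 511 and CHGA at 341 CPM, with UMIs in 73.7%, 65.8% and 73.7% of the cells, beside S100B at 726 CPM and VWF, an endothelial gene, at 136 CPM (26.3% of the cells). The other 33 had HES6 at 80.3, CHGA at 21.9 and S100B at 1653 CPM in sum. The median UMI count was 21898 in the 38 cells, 9671 in the 33 and 10452 in all kept cells. Median doublet scores were 0.0838 in the 38 and 0.0830 in the 33. Whether the 38 are doublets of tumour cells and other cells was not tested further. Macrophage-like cells, with C1QA, a complement subunit, at 1549 CPM, made up 1.21% (0.914% to 1.56%; 57 cells).

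Within the neuroendocrine-like cells, clusters differed in state genes. A cluster of 176 cells (3.72%, 3.20% to 4.30%) was led by TOP2A at 1157 CPM and MKI67 at 481 CPM, both of dividing cells. A cluster of 465 cells was led by CA9, a carbonic anhydrase induced by low oxygen, at 90.2 CPM, with LDHA and BNIP3, which respond to low oxygen as well. EGR4, EGR3 and NPAS4, immediate early genes of stimulated cells, led a cluster of 551 cells, and the heat shock genes HSPA6 and HSPA1A led 1 of 190 cells. For HSPA6, 2 of these 190 cells held 32.3% of the UMIs. The specimen was dissociated and frozen first, so for these 2 clusters a state of the tumour cannot be told apart from an effect of handling.

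Unnamed clusters held 19.2% of the human cells (18.1% to 20.4%), and from 15.3% to 24.3% over the barcode suffixes. The naming thresholds were set after the clusters had been seen. The largest, with 423 cells (8.95%), was led by SLPI, SERPINB3, KRT6A and KRT17, genes of squamous and secretory epithelium, and by HES1, a Notch-induced repressor. In that cluster 2 cells held 93.2% of the UMIs of KRT5, KRT6A, KRT17, SERPINB3 and SLPI together, and had 2 HES6 UMIs and 0 NEUROD1 UMIs. The other 421 cells held NEUROD1 at 668 and CHGA at 595 CPM, against 760 and 592 CPM in neuroendocrine-like cells, but HES6 at 1215.5 against 1981 CPM. Of the rest, clusters of 279 and 50 cells had few UMIs, 1 of 122 cells had low markers, and 1 of 34 cells mixed NKG7 and GNLY of T and NK cells with TPSB2 of mast cells, of which 2 cells held 78.6% of the UMIs.

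**Figure D4:**
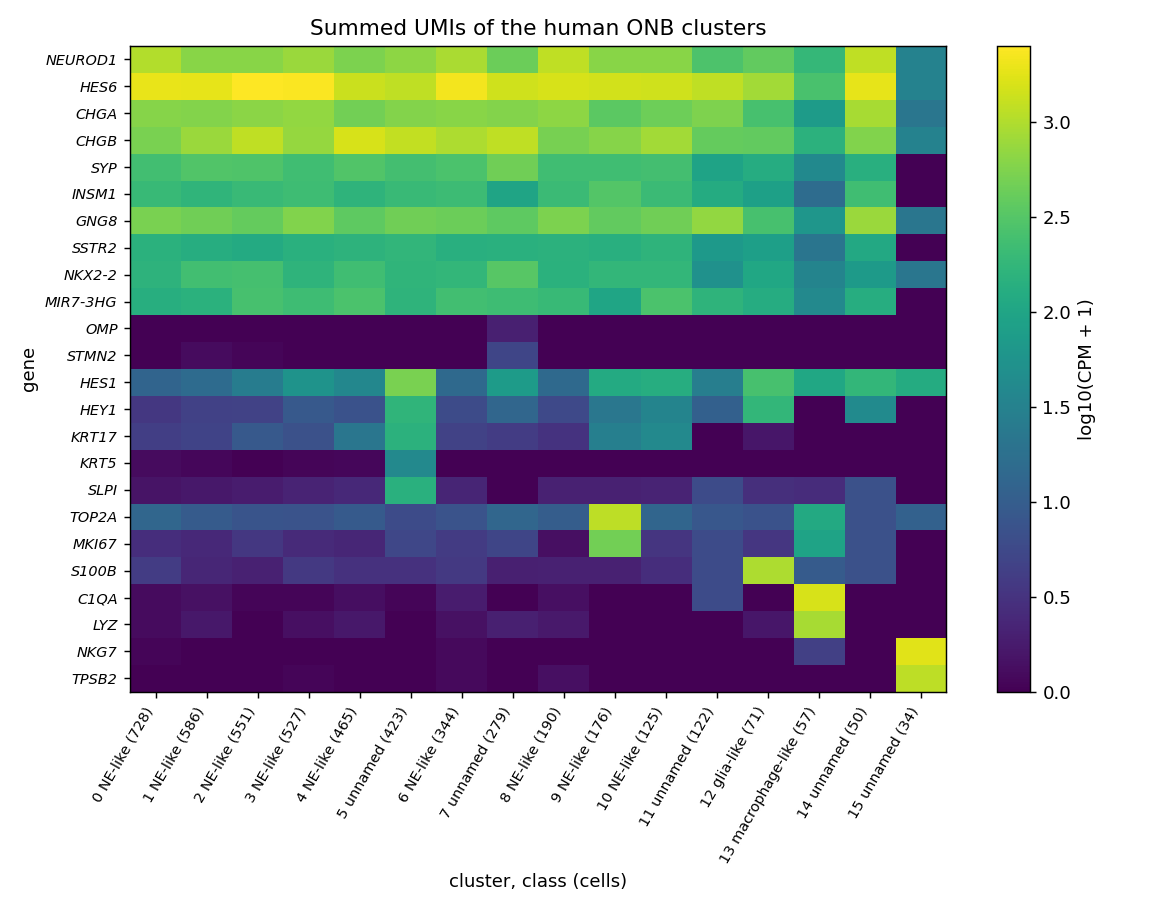
Summed UMIs of 24 genes in the 16 human clusters, as log10 of CPM plus 1; numbers of cells stand in parentheses. HES6, NEUROD1 and CHGA are high in the neuroendocrine-like clusters, and KRT5, KRT17 and SLPI in the unnamed cluster of 423 cells come mostly from 2 cells.

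The mouse signatures were then set against the human tumour cells. In neuroendocrine-like cells over the 162 cells of the glia-like, macrophage-like and mixed clusters, the median log2 ratio was 0.46 for the immature neuron signature (0.23 to 0.75 over resampled genes; percentile 99.75 of random lists), 0.43 for the globose basal signature (0.26 to 0.63; 99) and 0.42 for the mature neuron signature (0.13 to 0.87; 98.9). Horizontal basal genes stood at -0.32 (-2.50 to 0.23; percentile 0.1) and sustentacular genes at -0.20 (-1.14 to 0.12; 2.31). The genes that were higher in bulk ONB had a median of 0.48 (0.45 to 0.51; 1809 genes), and those that were lower had -0.23 (-0.30 to -0.17; 932 genes). The 162 base cells include the 38 glia-like ones in which most cells had UMIs of tumour genes (HES6 in 73.7%, NEUROD1 in 65.8% and GNG8 in 76.3%), and a base without these 38 was not tried. With all other cells as base, a setting chosen after seeing the data, the immature neuron value fell to 0.13. This is 1 specimen, so no test was made, and genes are not independent replicates.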

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

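Of the tests in this part, the doublet test of keratin genes was written before its result was seen, and the others were chosen after.

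Barcodes of the human ONB specimen that were left out only for their mitochondrial share held UMIs of tumour genes above the level that a count of 0 allows. In these 1769 barcodes HES6 stood at 914 CPM, NEUROD1 at 180 CPM, CHGA at 399.5 CPM, CHGB at 1077 CPM, INSM1 at 84.4 CPM and GNG8 at 207 CPM, against a limit of 0.640 CPM. In the kept cells HES6 stood at 1817, NEUROD1 at 723, CHGA at 577, CHGB at 915, INSM1 at 193 and GNG8 at 448 CPM. More than 3 UMIs of these 6 genes together were found in 66.5% of the barcodes (64.2% to 68.7%) and in 5.26% of macrophage-like cells (1.10% to 14.6%). The level of 3 UMIs was taken from the macrophage-like cells, as one that 90% of them do not exceed, so their share is low by construction. The share of the barcodes argues against free RNA as the whole source, as far as macrophage-like cells show the free RNA. The means were alike, 7.59 and 7.84 UMIs, with 407 of the 447 UMIs of macrophage-like cells in 2 cells, and whether the barcodes held damaged tumour cells stays open and untested.

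The split of the 6 bulk libraries into ONB and OM called 4170 genes, and the highest of the other 9 splits called 0 by edgeR (160 to 671 at an unadjusted p under 0.05). For the fixed lists the real value was 12 and the highest other 15, with 2 of the 10 splits giving as many, and for the mouse signatures it was 4 and 8, with 5 of the 10 giving as many. For genes 1 of the 10 splits, the real one, gave as many. With 10 splits the share cannot fall under 0.05, so for genes the splits cannot decide. For lists and signatures, splits that mix ONB with OM gave as many or more. The number of lists or signatures that passed therefore does not set the real split apart.

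Macrophage genes such as CD163 and MRC1 rose in ONB while T cell, B cell and plasma cell lists fell, though with an estimated correlation neither the myeloid list (adjusted p = 0.531) nor the 2 lymphoid lists (0.496 each) passed. A smaller share of all non-tumour cells in ONB would move them alike, but the myeloid mean minus the T and NK mean was 3.28 higher in ONB on the log2 scale, with an SD of 0.507 around the group means. It ran from -0.14 to 1.15 in the OM libraries and from 3.66 to 4.199 in the ONB libraries, which argues against that explanation. A single OM library rich in lymphoid cells is argued against as well, since without OM 3 the B and plasma list kept a median of -2.04. A change in the immune cells of the tumour, or a difference in where the biopsies were taken, stays open and untested.

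KRT14 and KRT5, the paired keratins of basal epithelium, stood at 822 and 919 CPM in ONB 5, a KRT14 to KRT5 ratio of 0.894. The highest ratio of an OM library was 0.0153, lower by 58.5 times, which argues against mucosa of the kind in the OM libraries as the source of KRT14. The ratio does not decide the source of KRT5. In ONB 5, KRT5 lay within the range of the OM libraries (442 to 2043 CPM), as did TP63 (29.9 CPM, against 27.45 to 174 CPM). Squamous epithelium or tumour cells with basal keratins may be the source of KRT14, and no test here separates them.

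In the single-cell specimen, keratin genes led a cluster of tumour-like cells. In that cluster 93.2% of the UMIs of KRT5, KRT6A, KRT17, SERPINB3 and SLPI lay in 2 cells with few tumour gene UMIs, as a few epithelial cells grouped with tumour cells would give. KRT17 was also found in cells with tumour genes. Barcodes with at least 3 UMIs of these genes together were taken over all kept cells, that cluster included. Their median tumour gene level was 87.5% of that of neuroendocrine-like cells, which argues against free tumour RNA in droplets of epithelial cells. Free epithelial RNA stays open: in neuroendocrine-like cells not low in tumour genes, KRT5, KRT6A, SERPINB3 and SLPI had 0.161 UMIs per KRT17 UMI (423 KRT17 UMIs in 151 cells), but the 2.24 it is set against comes from 2 cells, and the least number of such cells was set after these values were seen. Doublets cannot be told apart from tumour cells with KRT17, since 11.1% of 63 such barcodes (4.59% to 21.6%) were low in tumour genes, across the bound of 10% set for that test, as were 6 of 8 over the mitochondrial limit (75%, 34.9% to 96.8%).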

How the results depend on the processing

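The limit of 30% on mitochondrial UMIs, the base of all other cells and the renamed cluster were chosen after seeing the data. Upper-quartile scaling moved the median of all genes by -0.10. The cause was not tested for any change below, apart from fewer libraries (in the block, or where a library was left out) and cells that gained a class name. A group of 2 libraries is assumed to vary like the other.

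A test against a fold of 1.5 called 1156 higher and 1339 lower genes, fewer by its construction, and DESeq2 3240 and 3301. RLE and upper-quartile scaling, the filters, limma-voom and the removal of dominant genes stayed within 1.5 times, from 1836 to 2133 higher and from 1806 to 2294 lower. Without 1 library the counts ran from 569 (without OM 2) to 1909 (without ONB 2) higher and from 764 to 1749 lower.

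With the specimen number as a block, edgeR called 0 higher and 0 lower genes (3997 at an unadjusted p under 0.05), with 1 residual degree of freedom; limma-voom without the block called 2052 and 2036. The deviations of OM and ONB libraries of 1 number had correlations of 0.0030 and -0.168, and those of unlike number ran from -0.163 to 0.147. Only numbers 1 and 2 occur in both groups, so this check cannot tell whether the numbers pair. In this block KRT14 (-1.97) and STMN2 (-0.89) reversed, as did the fibroblast (camera adjusted p = 0.0197) and erythroid (0.726) lists, and 14 lists passed, against 12. The ranges given over the alternatives leave this block out.

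With an estimated correlation 0 of 28 lists and 0 of 12 signatures passed (0 lists at an unadjusted p under 0.05, 12 with the preset correlation), and fry passed 9 lists and 2 signatures. Without 1 library 10 to 13 lists and 3 to 5 signatures passed.

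With limma-voom NEUROG1 (-0.93) and STMN2 (-1.19) reversed. Without 1 library, NEUROG1 ran from -6.74 (without ONB 2) to 5.20, KIT from -1.44 to 0.0080 (without OM 3), KRT14 from -1.94 (without ONB 5) to 8.68, STMN2 from -3.79 (without ONB 1) to 1.33 and S100B from -0.41 (without ONB 2) to 1.59. None of these genes was past the threshold.

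Lists that did not pass and reversed without 1 library had adjusted p from 0.384 to 0.728 (list endothelial cells; reversed without OM 2 or ONB 2), 0.384 to 0.891 (fibroblasts; OM 3 or ONB 5), 0.171 to 0.983 (erythroid; ONB 1 or ONB 5) and 0.675 to 0.991 (list sympathetic neuroblastoma factors; ONB 5). So did the mature neuron signature, from 0.0744 to 0.904 (without OM 1), and the neutrophil signature, from 0.381 to 0.904 (without OM 1, OM 3, ONB 1 or ONB 2; 0.647 with 25 genes).

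The share of mouse cells of the neuronal lineage was 60.2%, 63.9% with a minimum of 2000 UMIs and 58.5% with doublets kept. The neuroendocrine-like share of human cells, 78.1%, was 79.7% at resolution 0.5, 94.7% with a minimum of 2000 UMIs, 72.5% with the limit of 30% and 87.0% with the keratin-led cluster counted as neuroendocrine-like. With the minimum of 2000 UMIs 4507 of the 4728 cells stayed, and the unnamed share was 2.68%, against 19.2% in the main setting. Much of the rise to 94.7% therefore came from cells that had been unnamed. The immature neuron ratio of neuroendocrine-like cells fell from 0.46 to 0.13 with all other cells as base.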

Other observations

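No test was made in this part, and its genes were chosen after their values were seen.

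HES1 and HEY1, targets of Notch signalling, were abundant in the unnamed human cluster once its 2 keratin-rich cells are set aside. In the other 421 cells HES1 stood at 519 CPM and HEY1 at 167 CPM, against 34.6 and 6.64 CPM in neuroendocrine-like cells. HES6, which counters HES1, stood at 1215.5 CPM against 1981 CPM, while CHGA (595 against 592 CPM) and GNG8 (458 CPM in both) were close.

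A mouse cluster of 52 unnamed cells held at high levels 3 genes whose human counterparts fell in bulk ONB. Bpifb3 stood at 91433 CPM, Bpifb6 at 10449 CPM and Scgb1c1 at 339970 CPM in these cells. Their human counterparts BPIFB3, BPIFB6 and SCGB1C1 are among the genes that fell most in ONB. Gpx6 and Bpifb4 led the cluster as well, and GPX6 (adjusted p = 0.0672) and BPIFB4 (0.0801) did not pass.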
